A study of Caenorhabditis elegans with 4 samples.

How the data were processed

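ChIP-seq was carried out on extracts of adult worms of the strain fem-2(b245) grown at 20 °C. Per the labels' protocols, ground frozen worms were fixed with 1% formaldehyde for 10 min, sheared by sonication, and precipitated with 5 µg of antibody. Fragments of 250 to 500 bp were taken from a gel, amplified for 18 PCR cycles and sequenced on Illumina instruments. The 4 libraries formed 2 groups by their titles, T09A5.8 ChIP (2 replicates) and input (2 replicates). Values were used for the ChIP libraries only, and the input libraries were not used here.

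The authors called peaks with MACS for each ChIP replicate and with MACS v2 for the series-level list, on WormBase build WS220, per the file headers and the source column of the deposited lists. The aligner, the use of the input libraries, the thresholds and whether replicates were pooled for the series-level list were not given in the sources used here. The only value per peak was the score that the authors deposited, whose definition no header states. Scores ran from 50.3 to 3233 and from 50.1 to 3233 in the replicate lists, and from 1.31 to 159 in the series-level list. They were therefore used to rank, filter and describe peaks within their own list. Across lists, the scores of the replicates were correlated over shared sites, and series-level scores were compared between groups of sites formed by replicate score. How peaks were called limits every comparison, because a peak list shows where enrichment passed a threshold and not how much protein was bound, and regions under the threshold are silent. The lists hold no read counts, so depth is unknown and no interval that needs it is given. Wilson 95% intervals on shares of sites cover counting error only.

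A site was the merged span of overlapping peaks (at least 1 bp) with at least 1 peak of each replicate. Chromosome lengths were taken as the largest peak end on each of the 6 chromosomes in any list, since no header gives lengths. The overlap of the replicates was tested against 1000 circular rotations of a list within its chromosomes (one-sided), and the share of autosomal sites with a midpoint in the arms, the outer of 3 equal parts of the chromosome, against 1000 rotations of the sites (two-sided). The correlation of scores used the highest score per site and replicate and 100000 permutations. The density on X was compared with the 5 autosomes by an exact permutation of chromosome labels. The share of wide and narrow sites in the arms was compared by 100000 permutations of width within chromosomes. The series-level list was described by counts. For the description of long stretches, series-level peaks were joined across gaps of up to 500 bp.

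The tests, the alternatives and the rule for named sites were fixed before the data were examined. The rule took the 10 sites with the highest mean over the replicates of the percentile of the highest score of the site within its list, given by coordinates, as it provides for peaks without an annotation of their build. The alternatives fixed then were an overlap of at least 50% of the shorter peak, only peaks above the median score of their list, each replicate alone, the series-level list, pairs of peaks in place of sites for the score correlation, and the outer of 4 equal parts as arms. Added after the data were seen were local shifts of 100 to 500 kb, shares of bases, series-level peaks joined across 1 kb, tied top scores, an exact permutation of which part is called central, and the comparisons of width and of left with right arms. The comparisons with gene starts, repeat-masked sequence, GC content and gene lists were not run. The gene names used here belong to assembly WBcel235, another build than that of the peaks, so they served only to give the symbol of T09A5.8, and no coordinates were converted.

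The rotation and correlation tests were checked on simulated data before use. Lists of randomly placed peaks were simulated in 100 runs. The list tested had 953 peaks, and the list it was set against had a similar number. The overlap test called 5% of unrelated pairs and the arm test 8% of uniform lists at 0.05, and both called 100% of the runs with a simulated effect. The correlation test was run once per case on 300 simulated sites, with a Spearman rho of 0.773 for a related pair and a permutation p of 0.051 for an unrelated pair. A simulated arm share of 90% was recovered as 90.0%. The simulated lists were not clustered as the real ones are, and these checks used fewer rotations and permutations than the tests of the data. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.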

Results

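T09A5.8 binding was profiled by ChIP-seq in Caenorhabditis elegans. T09A5.8, which carries the symbol cec-3 in the WBcel235 gene names, is a chromodomain protein, a class of proteins that bind methylated histone tails. The animals were fem-2(b245) hermaphrodites, staged as young adults that contained a germline and kept at 20 °C. fem-2 encodes a phosphatase of the sex determination pathway. Chromatin was precipitated with the affinity-purified rabbit polyclonal antibody SDQ4501 in 2 ChIP libraries, and 2 input libraries were also made. The measurements used here were 3 lists of peaks on genome build WS220, namely a list for each ChIP replicate and a series-level list. Each peak had a position and a score given by the authors, whose definition the lists do not state. No read counts accompanied the lists, so the depth of the libraries was unknown. No label stated that the 2 replicates came from separate cultures, so differences between them may be technical, and the p-values below describe these libraries alone. All intervals cover counting error only.

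The first question was where T09A5.8 was found in both replicates. Replicate 1 had 3810 peaks that covered 12.5 Mb, and replicate 2 had 4000 peaks that covered 13.2 Mb, a mean of 3905 ± 134 peaks and 12.8 ± 0.493 Mb (SD, n = 2). Merging the overlapping peaks gave 3117 sites held by both replicates, which spanned 12.7 Mb, or 12.7% of the chromosome length. These spans include bases in a peak of 1 replicate only, and 11.2 Mb lay in peaks of both. That was 89.7% of the peak bases of replicate 1 and 84.9% of those of replicate 2. The median site was 2620 bp wide, and 238 sites wider than 10 kb held 28.2% of the site bases. In replicate 1, 90.8% of the peaks (3461 of 3810) overlapped a peak of replicate 2, and in replicate 2, 83.8% (3351 of 4000) overlapped a peak of replicate 1. Rotating a list around its chromosomes gave mean overlaps of 25.2% and 23.8%, with a one-sided permutation p of 0.000999 in each direction, the smallest that 1000 rotations can give. Shifts of 100 to 500 kb, added after the data were seen, kept most peaks in their chromosome region and gave mean overlaps of 41.9% and 39.7%. Across the sites, which are not independent replicates, the highest scores of the 2 replicates had a Pearson r of 0.885 and a Spearman rho of 0.879, each with a permutation p of 1e-05, the smallest that 100000 permutations can give.

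Peaks found in a single replicate had lower median scores and widths than the shared ones. The 349 peaks seen only in replicate 1 had a median score of 86.1 and a median width of 1120 bp, against 425 and 2153 bp for its shared peaks. The 649 peaks seen only in replicate 2 had a median score of 106 and a median width of 1154 bp, against 660 and 2327 bp for its shared peaks. On the autosomes, 93.5% and 90.7% of these unshared peaks lay in the chromosome arms (the outer parts of a division of each chromosome into 3 equal parts), against 89.7% of the shared peaks in each replicate, a difference that was not tested.

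The next comparison set the X chromosome, which is regulated differently from the autosomes in the worm germline, against the 5 autosomes. T09A5.8 sites were sparse on X. X held 125 of the 3117 sites, or 4.01% (95% Wilson interval 3.38 to 4.76), but 17.7% of the chromosome length. X had 7.06 sites per Mb, whereas the autosomes averaged 37.1 and ranged from 28.3 on chromosome II to 51.9 on chromosome I. Sites covered 22.2% of chromosome I, 18.5% of chromosome III, 13.1% of chromosome V, 11.1% of chromosome IV, 10.4% of chromosome II and 2.87% of X. Per replicate, X carried 9.43 ± 1.28 peaks per Mb and chromosome II, the autosome with the fewest, carried 36.2 ± 2.27 (SD, n = 2), so the gap exceeded the spread between replicates. An exact permutation of the 6 chromosome labels gave a two-sided p of 0.167, the smallest this design allows, so the test could not reach 0.05.

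Within X, the sites were gathered toward the left end. That end was not covered evenly, since peaks covered 0.302% and 0.636% of the bases between 500001 and 1000000 in replicates 1 and 2. The leftmost 10% of X held 51 of its 125 sites, or 40.8%, and the leftmost 20% held 54.4% of the sites and 70.1% of their bases. Between 1500001 and 2000000 on X, peaks covered 42.8% ± 2.18 of the bases (SD, n = 2), compared with 48.0% to 59.1% in the densest windows of the autosomes. In the series-level list the order was reversed, with 75.3% in the X window and 44.3% to 67.0% in the same autosome windows, although 1 other window, 17000001 to 17500000 on chromosome V, reached 88.9%. Divided into 3 equal parts from left to right, X held 77, 14 and 34 sites. The windows and these cuts were chosen after the values were seen.

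A further comparison set the autosome arms, which in this species carry most of the repeats and of the histone H3 lysine 9 methylation, against the chromosome centres. The outer parts of the division into 3 were taken as the arms and the middle part as the centre. T09A5.8 sites lay mostly in the arms. Of the 2992 autosomal sites, 1351 had their midpoint in a left arm, 325 in a centre and 1316 in a right arm. The arms thus held 89.1% of the sites. Rotated sites gave a mean of 66.6%, with 95% of rotations between 47.9% and 82.6% (two-sided permutation p = 0.005). Of the autosomal peaks of each replicate, 89.9% ± 0.134 lay in the arms (SD, n = 2). Each autosome showed the pattern, with replicate means of 5.52 ± 0.181 times as many peaks per arm as in the centre on chromosome I, 4.46 ± 0.123 on V, 4.19 ± 0.0113 on IV, 4.07 ± 0.126 on II and 3.96 ± 0.0869 on III (SD, n = 2). Mappability, copy number and the input reads of the arms were not examined, so technical explanations of the arm share stay open.

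**Figure D1:**
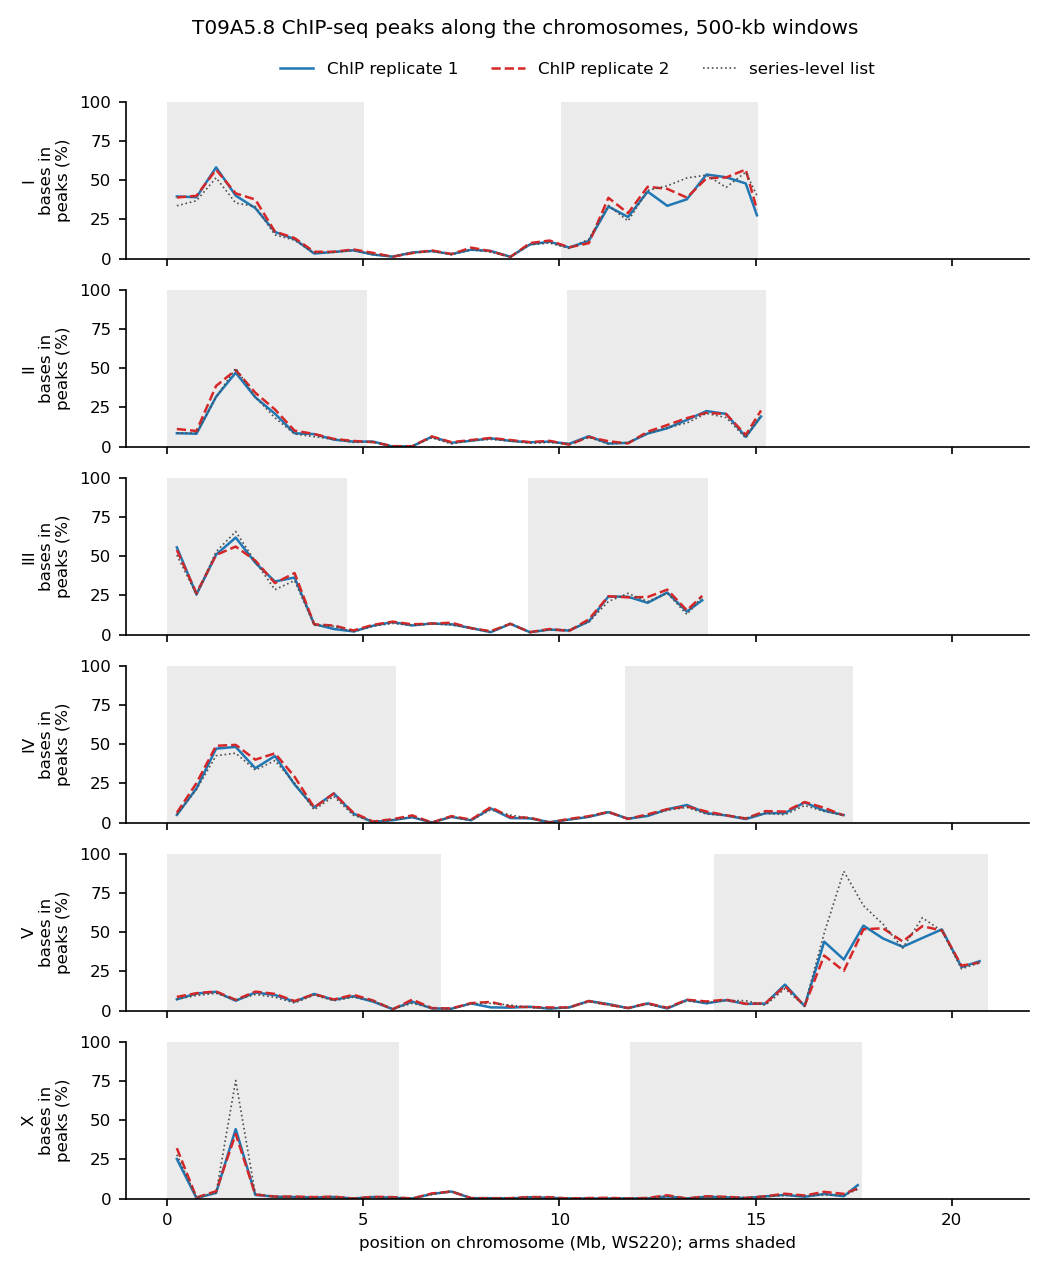
Share of bases in T09A5.8 peaks (y axis, percent) in 500-kb windows along the 6 chromosomes (x axis, Mb, WS220), for ChIP replicate 1 (solid blue), ChIP replicate 2 (dashed red) and the series-level list (dotted grey), with the arms of each chromosome shaded. Coverage is concentrated in the shaded arms, reaching a replicate mean of 59.1% on the left arm of chromosome III and 53.0% on the right arm of chromosome V, and on X it peaks near the left end at 42.8% in the replicates and 75.3% in the series-level list. The highest series-level window is 17000001 to 17500000 on chromosome V, with 88.9% against 32.6% in replicate 1 and 25.3% in replicate 2.

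The arms of a chromosome were not covered alike. The left arm held more peaks than the right on chromosome IV (2.57 ± 0.209 times as many), chromosome III (1.43 ± 0.0969), chromosome II (1.39 ± 0.0306) and X (2.45 ± 0.216; SD, n = 2). The right arm held more on chromosome V, with 2.92 ± 0.148 times as many peaks as the left, and on chromosome I, with 1.21 ± 0.0496. Each of these ratios lay further from 1 than the SD of the replicates, and none was tested, since the ratios were chosen after the data were seen. In bases, the sites covered 28.4% of the right arm of chromosome V but 7.65% of its left arm, and 23.3% of the left arm of chromosome IV but 6.61% of its right arm. On chromosome III the left arm was 34.6% covered and the right 15.4%. The centre was covered by between 3.25% and 5.43% on the autosomes and by 0.888% on X. For sites in place of peaks, the left to right ratio was 0.891 on chromosome I and 2.26 on X. Among sites built from peaks above the median score of their list it was 0.985 on chromosome I, close to equal, and 3.89 on X, and in the series-level list it was 3.49 on X.

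**Figure D2:**
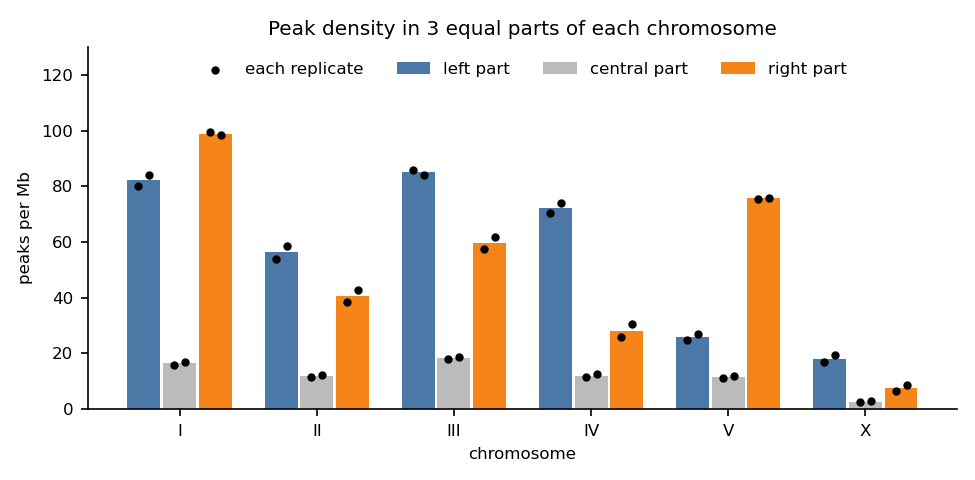
T09A5.8 peaks per Mb (y axis) in the left, central and right of 3 equal parts of each chromosome (x axis), with bars at the mean of the 2 ChIP replicates and a black point for each replicate. The central part is the lowest on every chromosome, and the higher arm is the left one on chromosomes II, III, IV and X and the right one on chromosomes I and V.

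The widest autosomal sites lay in the arms slightly more often than the narrowest. Of the 229 autosomal sites wider than 10 kb, 94.3% were in the arms (95% Wilson interval 90.5 to 96.7), compared with 88.5% of the 1059 sites of up to 2 kb (86.4 to 90.3). The difference was 5.84 percentage points, with a two-sided permutation p of 0.00896 when widths were exchanged within chromosomes. This comparison was chosen after the data were seen, and neighbouring sites are not independent. The call was lost in the peaks of replicate 2 alone (3.98 points, permutation p = 0.0756) and among sites built from peaks above the median score (0.466 points, permutation p = 1).

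The highest-ranked sites, by the mean percentile of their scores in the 2 replicates, were spread over 5 chromosomes. Of the 10, 9 lay in chromosome arms, which held 89.1% of all autosomal sites. The first was a site of 6336 bp at 1835188 to 1841523 on chromosome I, with scores of 3134 and 3214 in replicates 1 and 2. The next were 1821783 to 1829433 on X, 2210117 to 2231913 on chromosome IV and 17200694 to 17214420 on chromosome V. Chromosome IV also held 13502642 to 13509473 and 2748267 to 2757735, and chromosome III held 2390117 to 2396174. Chromosome I held 3 more, at 11684152 to 11688761, 13062341 to 13076903 and 9495265 to 9503323, the last being the only one of the 10 in a chromosome centre. The 10 sites were 4610 to 21797 bp wide. The ranking did not resolve the top of the lists, because 407 sites (13.1%) scored 3100 or more in both replicates, and sites above 3100 had a lower median series-level score than sites at it (36.4 against 53.4 in replicate 1 and 30.7 against 48.1 in replicate 2).

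The sites were also ordered by width and by series-level score, which was chosen after the values were seen. The widest site covered 45649 bp at 12486532 to 12532180 on chromosome I, followed by 41199 bp at 17217735 to 17258933 on chromosome V and 40422 bp at 1910608 to 1951029 on chromosome III. All 10 of the widest sites lay in arms, as did 94.3% of all autosomal sites wider than 10 kb. The chromosome III site also had the highest series-level score of any site, 159, and 5 of the 10 sites with the highest series-level scores were on chromosome III. A single one of those 10, at 7708332 to 7714146 on chromosome III, lay in a chromosome centre.

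The series-level list was then set against the replicate lists. It held more and narrower peaks over a similar length, with 15063 peaks of a median 380 bp over 12.9 Mb. Of these, 8099 (53.8%) overlapped peaks of both replicates, 1027 those of replicate 1 alone, 1905 those of replicate 2 alone, and 4032 (26.8%) overlapped neither. Conversely, 3797 peaks of replicate 1 (99.7%) and 3982 of replicate 2 overlapped the series-level list. The series-level peaks found in both replicates had a median score of 10.8, those found in 1 replicate 5.89 and those found in neither 4.62. The series-level list is not independent of the replicates, so these counts were not tested.

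Some series-level peaks that overlapped neither replicate had high scores and lay in long runs of series-level peaks. The longest run of series-level peaks joined across gaps of up to 500 bp spanned 84792 bp on the left arm of chromosome III, from 1468806 to 1553597. It held 21 series-level peaks, 18 of which overlapped no replicate peak, with scores as high as 140, the highest of any series-level peak found in neither replicate. Replicate 1 had 1 peak that reached into this stretch and replicate 2 had 0. The stretch was chosen after the values were seen. Mappability, copy number and the input reads of such stretches were not examined, so a technical origin stays open.

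**Figure D3:**
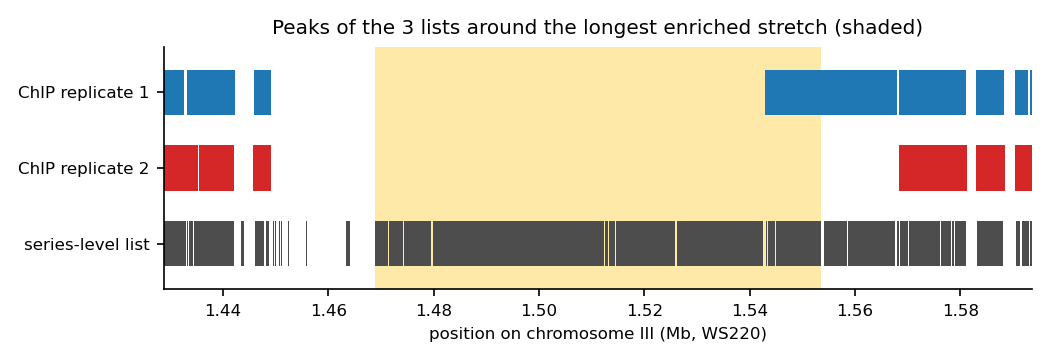
Peaks of ChIP replicate 1, ChIP replicate 2 and the series-level list (rows) along chromosome III (x axis, Mb, WS220) around the longest run of series-level peaks, shaded, at 1468806 to 1553597. Series-level peaks fill the shaded stretch almost completely, whereas the replicate lists resume only near its right end or beyond.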

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

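The comparison of wide with narrow sites, the left to right ratios, the local shifts, the shares of bases, the joining of series-level peaks, the tied top scores and the exact permutation of which part is called central were chosen after the data were seen. The replicate overlap, the score correlation and the arm share kept their direction and their side of 0.05 under every alternative run, with overlaps of 90.3% to 90.8% for replicate 1 and 83.0% to 84.7% for replicate 2, a Spearman rho of 0.747 to 0.881, and arm shares of 81.7% (outer of 4 equal parts as arms, against a rotation mean of 50.4%) to 91.5%, the share of bases in arms (91.0%) having no test. The share of sites on X ran from 3.02% to 5.63%, always below the 17.7% of length, but its exact test cannot pass 0.05 in any setting and so says nothing about stability. Keeping only peaks above the median score of their list lowered the sites from 3117 to 1624 and the series-level peaks found in either replicate from 73.2% to 65.2%. The first fall follows from the smaller lists. The second does too, because the filter also removed the weaker replicate peaks that series-level peaks could overlap. Against the full replicate lists, 26.8% of all series-level peaks were missing. With the series-level list split by score into 4 parts, that share was 12.9% in part 3 and 7.09% in part 4, the strongest. The stronger series-level peaks were thus found more often in the full replicate lists, not less. The greater arm share of wide sites was lost with the same filter (0.466 points, permutation p = 1) and without replicate 1 (3.98 points, permutation p = 0.0756), for causes not tested. It was kept without replicate 2 (4.73 points, permutation p = 0.0364). No left to right ratio changed direction, but with the same filter that of sites rose from 2.26 to 3.89 on X and from 2.45 to 3.61 on chromosome IV, and on X it was 3.49 in the series-level list. The planned comparisons with gene starts, soft-masked sequence, GC content and gene lists were not run under any setting. No paired analysis was possible because the input libraries, which share replicate numbers with the ChIP libraries, were not used here and no test compares the groups. Depth is unknown, so whether weak unshared peaks reflect fewer reads could not be examined.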

Other observations

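The tests of explanations, the stretches and the windows in this part were chosen after the results they bear on had been seen, whereas the shares of sites and of series-level peaks on X were planned. On the right arm of chromosome V, 12 runs of series-level peaks longer than 30 kb followed one another between 16833214 and 17646009, a region of 813 kb of which 74.9% lay in these runs. Replicate peaks covered 36.4% of the bases of the 12 runs, and 3 of the runs had no replicate peak at all. The whole series-level list had 28 runs longer than 30 kb, of which 15 were on chromosome V, 6 on chromosome I, 4 on X, 3 on chromosome III and 0 on chromosomes II and IV. All 28 lay in chromosome arms, where 88.8% of the runs of up to 5 kb also lay. The 4 on X lay between 1643428 and 2003971, where series-level peaks reached 75.3% of the bases of a 500-kb window on a chromosome that held 5.38% of the series-level peaks. Mappability, copy number and the input reads of the long runs were not examined, so technical explanations of the runs stay open.

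Strong series-level peaks were missing from both replicate lists in some of the longest runs, since replicate peaks covered under 50% of the bases of 15 of the 28 runs over 30 kb but over 95% of 10 others, and 86.01% of a run of 52520 bp on X. Enrichment too weak for the replicate lists may account for many of the weak missing peaks. The missing share fell from 51.1% in the lowest-scoring 25% of the list to 12.9% in the 25% just above the median. Among the highest-scoring 5%, 5.44% (41 of 754, 95% Wilson interval 4.03 to 7.29) were still missing, so the missing peaks were not confined to low series-level scores. The strength of these 41 by the measure of the replicate lists is unknown, since those lists were called with MACS and the series-level list with MACS v2. A limit on peak width in the replicate lists is argued against as the whole cause for the missing peaks of the highest-scoring 25%. Only 40.1% (34.4 to 46.1) of them lay in gaps that could hold a peak wider than the widest kept. They were counted wherever they lay, so this share does not settle the cause within the longest runs. A local background raised by the enrichment itself stays open. Of the highest-scoring 25%, 19.6% of the peaks with the most series-level coverage within 50 kb were missing, against 3.50% of those with the least. The parts between had 2.44% and 2.76% missing, so the share was raised only where coverage was highest. Peaks in long runs have high coverage around them, so this comparison largely restates the pattern and cannot decide its cause. The order of the outer parts was seen on 4 of the 6 chromosomes, and on 5 when each chromosome was split at its median coverage. That split was widest on X (32.7% above the median against 7.48% below) and chromosome V (25.99% against 4.17%), with 0.687% to 7.11% above the median elsewhere and the reverse order on chromosome IV, and no biological explanation was tested because the values came from 1 group.

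The score of 3100 was shared by 435 peaks of replicate 1 (11.4%) and 589 of replicate 2 (14.7%). A cap on the strongest peaks is argued against by the 43 peaks that scored above it. A candidate explanation is a p-value that became 0 in the computer and was given a fixed score, since the highest score in each list, 3233, equals the negative log10, times 10, of the smallest number that double precision can hold. The sites at 3100 also had a median series-level score higher by 16.97 in replicate 1 (permutation p = 0.0207) and by 17.4 in replicate 2 (permutation p = 0.00888) than those above it. Neighbouring sites are not independent. The series-level score of a site was the highest among its series-level peaks, of which a site held up to 20, so it can be higher where a site holds more of them. If a p-value of 0 is the cause of the shared score, sites at 3100 would rank above the sites scored higher, and no biological explanation was tested.

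X held 4.01% of the sites and, at 7.06 sites per Mb, had the lowest density of the 6 chromosomes. Regions under the threshold of the series-level list are silent, so enrichment of X there could not be examined. Enrichment on X just under the threshold of the replicate lists is argued against as the whole cause. X held 5.03% (95% Wilson interval 4.37 to 5.77) of the weakest 25% of the series-level list, far below its 17.7% of length. This part is not purely under that threshold, since 51.1% of it overlapped neither replicate and the rest overlapped a replicate peak. The share of X was 5.15%, 5.67% and 5.68% in the successive stronger parts of the list. Of the series-level peaks found in neither replicate, strong ones included, X held 6.60%, also below 17.7%, against 4.38% of those in both. In replicate 2 it held 7.40% of the unshared against 4.03% of the shared peaks (in replicate 1, 3.44% against 4.02%). Long runs on X absent from the replicate lists are argued against as the whole cause, because X held 5.51% of all series-level bases. Mappability, copy number and the share of X reads in the input libraries were not examined, so technical explanations stay open, and no biological explanation was tested, since the design has no group without a germline or with another target.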
